A study of Mus musculus with 12 samples.

How the data were processed

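H3K79me1 and H3K79me2 were measured by ChIP-seq in mouse embryonic fibroblasts on day 4 of reprogramming, with 2 control (AF10 fl/fl, empty virus) and 2 Cre libraries per mark. Per the labels' protocols, chromatin was sonicated to 200 to 400 bp, and 7.1 µg was mixed with 133 ng of chromatin of human 293T cells, an embryonic kidney line, as a spike-in before precipitation with 5 µg of antibody. Per the labels' protocols, the cells grew on feeder fibroblasts, whose chromatin may be present in each library. Samples were grouped by their titles. The 4 RNA polymerase II libraries are not analysed here.

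The submitters' processing notes name Bowtie2, SAMtools 1.2, MACS2, HOMER, deepTools and bedtools, and the builds mm9 and hg19, with no role or order. The deposited peak names record a broad call of each library against an input, with a p setting of 0.001 for H3K79me1 and 1e-04 for H3K79me2, so the marks were not compared by their number of peaks. Each deposited list gives, per peak, the authors' fold enrichment (a ratio to background), −log10 p-value, −log10 q-value and a score, which equalled the whole part of 10 times −log10 q in every peak. These values are the authors' own and were used mainly to rank and filter peaks within a list. The deposited −log10 p reached down to about 1, and the smallest gap between peaks was 201 bp in all lists. No spike-in scaling is recorded in the lists. A peak list shows where signal passed a threshold, so a change of level over the whole genome need not appear in it.

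Positions are in mm9, printed from base 1. The last peak on chromosome 1 ended at 197185597, beyond the last gene end of 195291439 in the reference table, which is of another build (GRCm38.p6). No gene could therefore be tied to a peak, and 13 planned gene lists were not tested. Windows of 50 kb took the place of genes, as had been set for this case.

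Covered length was the sum of a library's peaks. Chance shares used the sum of the last peak ends per chromosome, 2641 Mb. Covered length, peak number and median width were compared on the log2 scale by exact permutation tests, two-sided unless stated, with 6 arrangements per mark and 36 over both. Retention was the share in bases of the length covered in both controls that a Cre library also covered. The covered share of 50 kb windows with a mean of at least 0.1 was tested with limma (empirical Bayes with a mean-variance trend, Benjamini-Hochberg at 0.05). The interaction of Cre and mark was fitted over all 8 libraries.

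Regions were named by a rule set before the data were examined. It took, per mark, the 5 windows with the largest fall (both Cre below both controls, both controls at least 30%), the 5 with the largest rise (both Cre above both controls), and the 3 widest domains common to both controls and to both Cre libraries. No H3K79me2 window met the rule for a fall. Other settings chosen before the data were examined were stricter p-values, equal peak numbers, merging within 1 kb, a minimum width of 1 kb, autosomes, other overlap rules, other scalings, minimum covers and windows of 10 kb, the replicate number as a block, and each library left out. Others were added after seeing the data, as said where they appear.

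The limma fit was tested on simulated data. With 200 windows shifted by 30 percentage points, it recovered 0 at the real spread and 200 with the spread multiplied by 0.1, in 2775 H3K79me2 windows and in 4223 H3K79me1 windows. Read depth is unknown, so precision could be judged only from the spread between libraries. The work used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1, Matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.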

Results

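The series asked how AF10, also called Mllt10, a cofactor of the H3K79 methyltransferase DOT1L, bears on the identity of fibroblasts that are being reprogrammed. Mouse embryonic fibroblasts with floxed AF10 alleles and doxycycline-inducible reprogramming factors (OCT4, SOX2, KLF4 and MYC) received an adenovirus that carried Cre recombinase, which deletes the floxed allele, or an empty adenovirus. Doxycycline at 2 µg/mL followed 2 days later, and chromatin was taken on day 4 of reprogramming. H3K79me1 and H3K79me2, the mono- and dimethylated forms of histone H3 lysine 79 found over transcribed gene bodies, were measured by ChIP-seq. Each mark had 2 control and 2 Cre libraries, 8 in all, and 4 further libraries for RNA polymerase II are not analysed here.

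The 8 peak lists together held 933917 peaks, called separately in each library. H3K79me1 peaks numbered 160119 and 156506 in control replicates 1 and 2, and 117816 and 12155 in Cre replicates 1 and 2. H3K79me2 peaks numbered 92184 and 194520 in the controls and 76497 and 124120 after Cre. Read counts are not given by the lists, so the depth of each library is unknown and no counting interval could be computed. The shortest peak differed between lists. It was 222 and 107 bp in the H3K79me1 controls, 164 and 50 bp in H3K79me1 Cre, 51 and 116 bp in the H3K79me2 controls and 147 and 126 bp in H3K79me2 Cre. No label states that replicates came from separate cultures, so a p-value measures the spread between these samples only, which may be technical.

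H3K79me1 was called over less of the genome in the Cre libraries on average, by an amount that rested largely on 1 library. Peaks covered 117.8 and 53.5 Mb in control replicates 1 and 2, and 60.1 and 1.86 Mb in Cre replicates 1 and 2. The group means were 85.7 ± 45.4 Mb (SD, n = 2) in control and 31.0 ± 41.2 Mb (SD, n = 2) after Cre, and the geometric mean was 7.51-fold lower, a log2 difference of -2.91. Cre replicate 1 lay between the 2 controls, so the groups overlapped. The exact two-sided permutation test over 6 arrangements gave p = 0.667, and the smallest p that 2 against 2 allows is 0.333. Without Cre replicate 2 the log2 difference was -0.40. Peaks past a fixed p-value were not fewer in that library. At −log10 p of at least 3 it held 351 peaks, against 42 in Cre replicate 1 and 100 and 201 in control replicates 1 and 2. Those peaks were 2.89% of its list and at most 0.128% of each other H3K79me1 list, so all 4 lists held mostly weaker calls. The most frequent −log10 p was 2.25 in Cre replicate 2, 1.29 in Cre replicate 1, and 1.06 and 1.63 in control replicates 1 and 2. A fixed p therefore need not mark the same strength in each list. With only peaks of −log10 p of at least 5, the log2 difference in covered length was -1.32.

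H3K79me2 covered length did not differ between the groups by more than the spread between the controls. Peaks covered 16.0 and 71.5 Mb in control replicates 1 and 2, and 48.0 and 50.1 Mb in Cre replicates 1 and 2. The means were 43.8 ± 39.3 Mb (SD, n = 2) and 49.0 ± 1.45 Mb (SD, n = 2), and both Cre values lay between the 2 controls. The log2 difference of 0.53 had an exact two-sided permutation p of 1. Without control replicate 1 it became -0.54. It was also negative, at -3.30, when only peaks with −log10 p of at least 5 were kept, which left 5178 and 134 peaks in the controls and 5 and 73 after Cre.

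**Figure D1:**
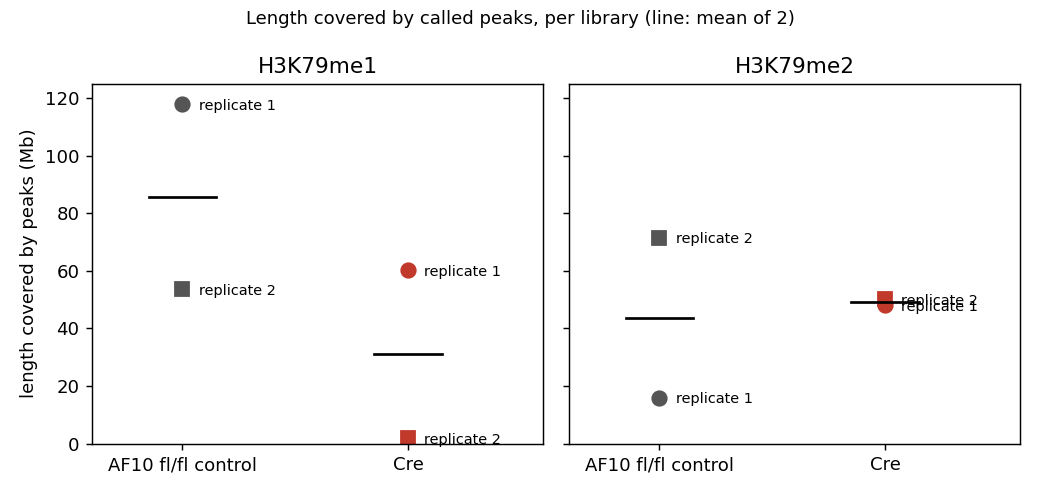
Length covered by called peaks in Mb (vertical axis) for each library of H3K79me1 (left) and H3K79me2 (right), control in grey and Cre in red. Circles are replicate 1, squares replicate 2 and the line is the mean of 2 libraries. H3K79me1 Cre replicate 2 stands at 1.86 Mb and the 2 H3K79me2 controls at 16.0 and 71.5 Mb.

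Over both marks together, the covered length differed by a log2 value of -1.19 between Cre and control. The stratified exact permutation test over 36 arrangements gave a two-sided p of 0.611, with 0.0556 as the smallest value it can reach. The strata may share chromatin, which would make the marks less than independent.

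H3K79me1 peak number was lower in both Cre libraries than in both controls, with means of 158312 ± 2555 in control and 64986 ± 74714 after Cre (SD, n = 2, log2 difference -2.07, exact permutation p = 0.333). H3K79me2 median peak width was greater in both Cre libraries, at 350 and 229 bp against 89 and 194 bp (log2 difference 1.11, exact permutation p = 0.333). Both p-values are the smallest that the design allows and neither passes 0.05. Median width had the same order as the shortest peak within each mark. For H3K79me2 the shortest peak was 51 and 116 bp in control replicates 1 and 2, and 147 and 126 bp in Cre replicates 1 and 2. A greater width after Cre therefore cannot be told apart from a difference in the peak call. H3K79me2 peak number differed by a log2 value of -0.46 and H3K79me1 median width by -0.77, each with overlapping groups and an exact permutation p of 0.667. Without control replicate 2 the difference in H3K79me2 peak number became 0.08, and without control replicate 1 that in H3K79me2 median width became 0.55. Without Cre replicate 2 the H3K79me1 differences became -0.43 in number and -0.05 in median width.

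**Figure D2:**
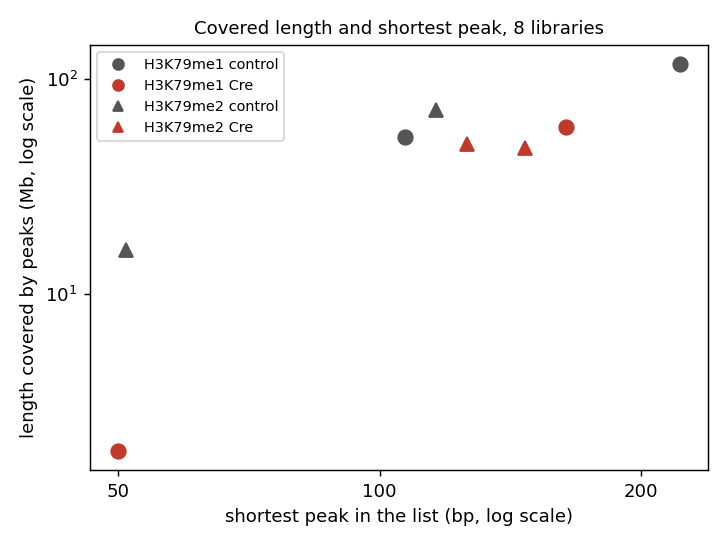
Length covered by peaks in Mb against the shortest peak of the list in bp, both on log axes, for 8 libraries; circles are H3K79me1, triangles H3K79me2, grey control and red Cre. The lists whose shortest peak is 50 or 51 bp cover 1.86 and 16.0 Mb, less than every other list.

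Most of the H3K79me2 called in both controls was also called after Cre, but that share depended on control replicate 1. H3K79me1 was retained in part. The length shared by both H3K79me2 controls, 12.1 Mb, was covered to 74.7% in Cre replicate 1 and 78.5% in Cre replicate 2, against 1.82% and 1.90% expected by chance from the covered share of the genome. The length shared by both H3K79me1 controls, 32.4 Mb, was covered to 49.4% in Cre replicate 1 and 2.46% in Cre replicate 2, against 2.28% and 0.0704% by chance. Between the controls, H3K79me2 control replicate 2 covered 75.6% of control replicate 1 and was covered by it to 16.9%. H3K79me1 control replicate 1 covered 60.4% of control replicate 2 and was covered by it to 27.5%. Retention depends on how much was called, and without H3K79me2 control replicate 1 the mean retained share of that mark was 44.4% rather than 76.6%. When any 2 libraries of a mark were taken as the reference pair, the mean share found in the other pair ran from 50.3% to 87.7% for H3K79me2 and from 20.0% to 70.0% for H3K79me1. The control pair is among these pairs, and its values of 76.6% and 25.9% were neither the lowest nor the highest of their mark. H3K79me2 pairs that included control replicate 1 gave 76.6% to 87.7%, with the control pair the lowest of them. Pairs without that list gave 50.3% to 54.7%. Reference lengths also differed between pairs, from 10.0 to 31.9 Mb for H3K79me2 and from 1.05 to 42.0 Mb for H3K79me1.

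Broad control domains were covered more completely in the Cre libraries than narrow ones. The controls were not compared with each other by width, so this order is not shown to be particular to Cre. As listed, control domains under 2 kb were covered to 74.2% and 78.1% in H3K79me2 Cre replicates 1 and 2, and the 106 domains of 2 to 5 kb to 98.3% and 97.3%. For H3K79me1 the shares were 49.3% and 2.39% under 2 kb, and 68.0% and 9.87% in 123 domains of 2 to 5 kb. No domain was wider as listed. With control peaks within 1 kb merged, 54.6% of the H3K79me2 length in domains under 2 kb was covered in Cre replicate 1. In Cre replicate 2 it was 58.1%. At 2 to 5 kb the shares were 75.3% and 69.5%, a smaller gap than between the same classes as listed. In the 20 domains of 20 kb and over, a class empty as listed, they were 91.8% and 88.0%. H3K79me1 in Cre replicate 1 went from 32.9% to 57.4% over the same classes, the widest of which held 13 domains, and reached 52.6% in the 390 domains of 10 to 20 kb. In H3K79me1 Cre replicate 2 the share was 1.23% in the narrowest class and 2.40% in the widest.

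**Figure D3:**
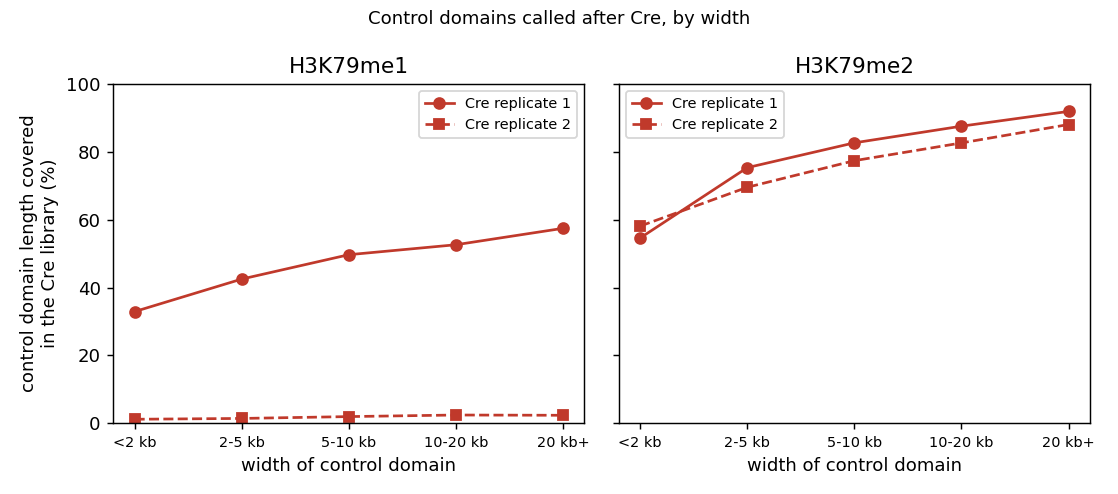
Percent of control domain length covered by peaks of each Cre library (vertical axis) by width of the control domain (horizontal axis), with control peaks within 1 kb merged, H3K79me1 left and H3K79me2 right; solid lines are Cre replicate 1 and dashed lines Cre replicate 2. H3K79me2 runs from 54.6% to 91.8% in Cre replicate 1, and H3K79me1 Cre replicate 2 stays at or under 2.48%.

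The 3 widest H3K79me2 domains common to both controls, on chromosome 10 at 126416239 to 126420809, chromosome 8 at 87318741 to 87323220 and chromosome 9 at 21421623 to 21425887 (mm9), were covered to 100% in both Cre libraries. The 3 widest common to both Cre libraries lay on chromosome 15 at 72992418 to 73015328, chromosome 17 at 27739467 to 27758580 and chromosome 4 at 154575028 to 154591525, with 75.9%, 70.6% and 70.8% of their length covered in control replicate 1 and 98.8%, 100% and 98.0% in control replicate 2. For H3K79me1, the widest control domain, on chromosome 8 at 19787992 to 19792019, was covered to 68.9% in Cre replicate 1 and 81.6% in Cre replicate 2. The next, on chromosome 7 at 127989689 to 127993675, was covered to 100% and 1.53%, and that on chromosome 4 at 148466527 to 148470163 to 58.9% and 13.9%. The 3 widest H3K79me1 domains common to both Cre libraries spanned 1843 bp on chromosome 8 at 19891056 to 19892898, 1369 bp on chromosome 4 at 149887774 to 149889142 and 1320 bp on chromosome 8 at 19790050 to 19791369. All of them were covered to 100% in control replicate 1, and to 20.9%, 83.0% and 100% in control replicate 2.

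In windows of 50 kb, H3K79me1 cover was lower in the Cre libraries as listed, again largely through Cre replicate 2. Of 4223 windows with a mean cover of at least 10%, 1773 (42.0%) had both Cre libraries below both controls and 0 had both above. If the 4 libraries were exchangeable in each window, 16.7% would fall in each direction. They were not, since Cre replicate 2 covered only 1.86 Mb in all. These shares therefore largely reflect the cover of whole libraries. The mean cover of the 4223 windows was 27.2% in control and 10.6% after Cre. The difference was negative in 99.3% of windows, with a median of -15.9 percentage points, and in 77.4% with a median of -6.90 without Cre replicate 2. It was negative in 50.9% after centring on library medians and 50.6% after quantile normalization. Both steps remove differences in level between whole libraries, so these 2 shares follow largely from the steps themselves. Windows are not independent, and limma with Benjamini-Hochberg adjustment at 0.05, taking the libraries as unpaired, called 0 of them changed, with 1 at an unadjusted p under 0.05. Tested on simulated H3K79me1 windows of the real spread, the same fit recovered 0 of 200 windows shifted by 30 percentage points, so a count of 0 does not exclude changes of that size. The count also depended on taking the libraries as unpaired. With the replicate number as a block, most of the windows were called lower, as given in the part on processing, but whether the numbers mark pairs is not known.

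The 5 windows with the largest H3K79me1 difference began at 133300001 on chromosome 1, 14150001 on chromosome 13, 65550001 on chromosome 9, 57800001 on chromosome 10 and 16350001 on chromosome 19 (mm9). On chromosome 1 the cover was 54.8 ± 16.6% in control and 12.2 ± 15.9% after Cre (SD, n = 2), and on chromosome 13 it was 54.2 ± 14.0% and 12.7 ± 14.2%. Differences in the 5 windows ran from -42.6 to -40.2 percentage points, and cover in Cre replicate 2 was at most 2.67%. The 5 largest values in the other direction were small. They began at 67000001 on chromosome 7, 15100001 on chromosome 5, 3000001 on chromosome 17, 4250001 on chromosome X and 3000001 on chromosome 11, with differences of 5.44 to 2.32 percentage points. H3K79me1 control replicate 1 listed 0 peaks on chromosome X, so the rise in that window may come from an incomplete list.

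For H3K79me2, 254 of 2775 windows (9.15%) had both Cre libraries above both controls and 3 had both below. Exchangeable libraries would give 16.7% in each direction. Here the controls covered 16.0 and 71.5 Mb, on either side of both Cre lists, so these shares also largely reflect whole libraries. Mean cover was 17.6% in control and 23.2% after Cre. limma called 0 windows changed at an adjusted p of 0.05, with 0 at an unadjusted p under 0.05, and recovered 0 of 200 simulated shifts of 30 percentage points at the real H3K79me2 spread. Leaving out control replicate 1 gave 530 calls, 522 of them lower, and leaving out control replicate 2 gave 2705, all higher, so these calls followed the retained control. In both fits the lone control is assumed to vary as little as the 2 Cre libraries, which gave the whole estimate of the spread.

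The 5 windows in which H3K79me2 was highest after Cre relative to control began at 45500001 on chromosome 4, 111300001 and 126750001 on chromosome 8, 125600001 on chromosome 5 and 117150001 on chromosome 11 (mm9). On chromosome 4 the cover was 23.2 ± 27.2% in control and 52.8 ± 4.98% after Cre (SD, n = 2), with 3.98% in control replicate 1 and 42.5% in control replicate 2. The 5 differences ran from 29.6 to 27.6 percentage points.

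The differences were spread over the chromosomes. On the ratio of group means, H3K79me1 cover was lower after Cre on 19 of 19 autosomes, from a log2 value of -1.67 on chromosome 13 to -1.32 on chromosome 8, but only -0.71 to -0.37 without Cre replicate 2. H3K79me2 cover was higher on 19 of 19, from 0.06 on chromosome 18 to 0.26 on chromosome 8, and lower on 19 of 19, from -0.66 to -0.44, without control replicate 1. These left-out values were chosen after seeing the data. On the X chromosome H3K79me2 gave -0.50. H3K79me1 control replicate 1 listed 0 peaks there, so the chromosome-wide X value of that mark is not used here. That list ended with chromosome 9 in its order and may be incomplete.

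The difference between the marks in their response to Cre was tested in 3479 windows. The interaction term was negative in 3457 of them (99.4%), with a median of -20.3 percentage points, but limma called 0 at an adjusted p of 0.05 and 58 had an unadjusted p under 0.05. In a fit chosen after seeing the data that left out H3K79me1 Cre replicate 2 and H3K79me2 control replicate 1, the median was -1.51 percentage points over 4408 windows and 0 were called, with 1 at an unadjusted p under 0.05. The peak names record different p settings for the marks, but the listed −log10 p reached down to about 1 in every list of both. Whether the settings enter this comparison is therefore not known.

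The marks lay together in both groups. Of the H3K79me2 length, 59.4% and 60.6% in control replicates 1 and 2 lay inside control H3K79me1 peaks, and 64.9% and 53.1% in Cre replicates 1 and 2 lay inside Cre H3K79me1 peaks, against 5.26% and 2.31% by chance. The group means were 59.99 ± 0.876% in control and 59.0 ± 8.28% after Cre (SD, n = 2). Their difference of -0.999 percentage points was slightly larger than the SD of the controls and well below that of the Cre libraries. In the other direction, 32.5% and 44.0% of the control H3K79me1 length lay inside control H3K79me2 peaks, and 60.1% and 77.9% of the Cre H3K79me1 length inside Cre H3K79me2 peaks. Regions common to all 8 lists numbered 2393 and spanned 251.6 kb.

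H3K79me1 cover was higher in windows with more H3K79me2 in all 4 H3K79me1 libraries. In classes of mean H3K79me2 cover that were chosen after seeing the data, with no minimum on H3K79me1, cover went from 1.08% where H3K79me2 cover was under 2% (40894 windows) to 52.3% where it was 30% or more (408 windows) in control replicate 1, and from 0.315% to 45.0% in Cre replicate 1. The ratio of Cre replicate 1 to control replicate 1 went from 0.293 to 0.862 over these classes, and that of Cre replicate 1 to control replicate 2 from 0.904 to 1.58. The ratio of control replicate 2 to control replicate 1 also went up, from 0.324 to 0.546. In percentage points the gap between the control and Cre means went from 0.551 in the lowest class to 16.9 in the highest, but its order depended on the choice of windows. With classes from the control H3K79me2 lists alone it was 16.2 at 10 to 30% and 16.0 at 30% and over, and in windows with a mean H3K79me1 cover of at least 10% it was flat, between 16.4 and 17.0.

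**Figure D4:**
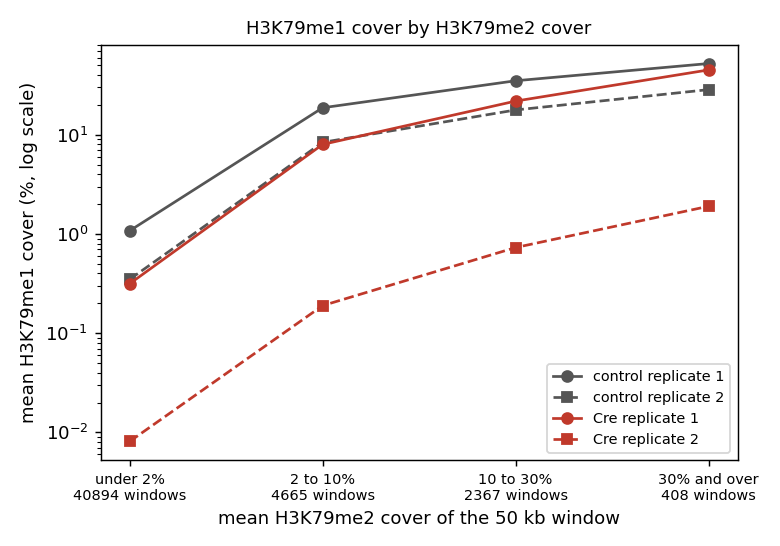
Mean H3K79me1 cover in percent on a log axis for each library (grey control, red Cre, solid replicate 1, dashed replicate 2), in 50 kb windows with a peak in any list, grouped by their mean H3K79me2 cover over 4 lists. Cover in Cre replicate 1 goes from 0.315% to 45.0%, and in control replicate 1 from 1.08% to 52.3%.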

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

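All exact-test p-values stayed above 0.05 in every alternative. Two-sided tests could not pass it here, but the one-sided test for a lower covered length over both marks could have (exact permutation p = 0.306). Of 101 alternatives, 85 kept direction and call or, for untested shares, moved by under 1 SD between replicates (33.2 points for H3K79me1 retention). H3K79me2 covered length changed direction at −log10 p of at least 5, with a log2 difference of -3.30. That cutoff need not mark the same strength in each list. With each library left out, H3K79me2 covered length ran from -0.54 to 1.61. With each library left out, H3K79me2 peak number ran from -0.997 to 0.080, and the median over autosomes, run after seeing the data, from -0.52 to 1.62. Mean H3K79me2 retention was 40.7% at −log10 p of at least 10, where Cre replicate 1 has 0 peaks and so counts as 0, and moved to 86.5% with peaks within 1 kb merged, 66.2% as domains overlapped by at least 1 base and 61.2% as domains overlapped over at least 50% of their length, and ran from 44.4% to 78.5% with each library left out. The H3K79me2 retention difference between the widest and narrowest classes was 21.7 points as listed and 33.6 with control peaks within 1 kb merged. The widest class was 2 to 5 kb as listed and 20 kb and over when merged, so the 2 values are not alike. With 1 library left out, H3K79me1 covered length ran from -5.42 to -0.40 and retention from 2.46% to 49.4%, all among the 85, a loose count. Both rested largely on Cre replicate 2.

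limma calls changed from 0 to 28 H3K79me2 windows, all higher, with no minimum cover, and ran from 0 to 2705 with each library left out. H3K79me1 calls changed from 0 to 9, all higher, after centring on library medians. Under that centring the share of H3K79me1 windows with a negative difference went from 99.3% to 50.9%, and for H3K79me2 from 8.87% to 48.5%, a move that follows largely from the centring itself.

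The replicate numbers were not taken as pairs, because no label ties a number to a shared culture. The deposited peak names do carry a tag (A, B or 19) that control and Cre libraries of the same mark and number share, whose meaning is not given, so the choice between the fits stays open. Same-numbered libraries deviated together in H3K79me1 (correlation over windows 0.51) and in opposite directions in H3K79me2 (-0.40). With the number as a replicate block, limma called 3365 H3K79me1 windows, 3364 of them lower, against 0 without it, and 0 H3K79me2 windows; the block left the log2 difference over both marks at -1.19 (exact sign-flip p = 0.625) and the interaction at 0 calls. A crossed replicate block for H3K79me2, added after seeing the data, gave 0 calls. Also added then, leaving out the library of each mark with the narrowest shortest peak gave a log2 difference over both marks of -0.47 (exact permutation p = 0.444).

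Peaks at −log10 p of at least 10 were absent from H3K79me2 Cre replicate 1 and from 3 H3K79me1 lists, so covered length, number and width gave no value there, nor did H3K79me1 retention or the limma fits. The interaction gave none at −log10 p of at least 5. Gene lists were not run, with or without a block.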

Other observations

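H3K79me2 control replicate 1 listed 421 sites with −log10 p of at least 10, of median width 69 bp against 89 bp for its whole list. Peaks overlapped 419 of them in control replicate 2, 415 in Cre replicate 2 and 132 in Cre replicate 1, and between 13 and 109 in the H3K79me1 lists. The site with the highest −log10 p, on chromosome 4 at 154321020 to 154321303 (mm9), had an authors' fold of 17.0 in control replicate 1, 13.2 in control replicate 2, 11.2 in Cre replicate 2 and 3.82 in Cre replicate 1. Chromosome Y peaks numbered 45, 52 and 29 in H3K79me2 control replicate 1, control replicate 2 and Cre replicate 2, and 0 in the other 5 lists.

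The tests in the next paragraphs were chosen after the results were seen, except the comparison at matched length. Its prediction was written before its result, but for another length, as said there.

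The first pattern is the wide range of covered length among lists of the same mark. Background read density was judged from each list's most frequent p. Read as the Poisson probability of more than 1 fragment, it gave 2.20 fragments per kb of shortest peak width in all 8 lists (coefficient of variation 0.000427%). Read as the probability of at least 1 fragment, the background varied by 40.5%. Agreement that close, over shortest peaks from 50 to 222 bp, favours the first reading. Under it, the values argue against a differing background density in the peak call of these 8 lists. They come from the call and not from read counts, so they do not show whether the background of the libraries themselves differed. The fragment length used in the peak call, read from the shortest peak, may contribute, with Pearson r = 0.86 (permutation p = 0.00285, adjusted 0.0057) and Spearman rho = 0.714 (permutation p = 0.0576, adjusted 0.0576) over 8 libraries. The relation rests partly on 2 lists that stand apart near 50 bp: over the other 6, r = 0.69 (permutation p = 0.122), and without the 2 farthest from the median width, r = 0.88 (permutation p = 0.1) and rho = 0.31. With the slope on shortest width removed, the Cre libraries were lower by a log2 value of -1.25 over both marks (exact permutation p = 0.0556, the smallest possible), but p was 0.111 with the slope fitted within groups and 0.167 with a slope of 1, and the value was -0.46 without H3K79me1 Cre replicate 2 and -0.60 without the 2 lists of shortest width, so AF10 deletion and fragment length cannot be told apart with 8 libraries.

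The second pattern is that H3K79me1 called after Cre lay more inside H3K79me2 regions. Against the union of the 4 H3K79me2 lists, the share was 45.8% and 56.4% in the controls and 68.1% and 87.6% after Cre, an order that 2 against 2 gives with an exact permutation p of 0.333 at best. Part of it may come from shorter lists holding only the strongest peaks. With lists shortened to 53.5 Mb by −log10 p, the controls reached 67.5% and 56.4% and Cre replicate 1 stood at 70.7%. That was 3.12 percentage points above the higher control, less than the controls differed. The written prediction named the length of Cre replicate 1, 60.1 Mb. The length used was that of control replicate 2, so that list was not shortened. With all 4 lists shortened to 1.86 Mb the shares were 82.4% and 74.5% in control and 94.0% and 87.6% after Cre. There Cre replicate 1 exceeded the higher control by more than the controls differed, so the answer depended on the length chosen. Fragment length and AF10 deletion stay open: as listed, Cre replicate 1 exceeded the higher control by 11.8 percentage points although its shortest peak lay between theirs, but that is 1 library.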
